A study of Mus musculus with 3 samples.

How the data were processed

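The study measured gene expression in single mouse cells by droplet RNA sequencing (Chromium, 3′ end counting with unique molecular identifiers, UMIs). The authors deposited 3 libraries, 1 per group. They came from bone marrow enriched for megakaryocytes, from lung enriched for megakaryocytes, and from total lung. Per the labels' protocols, lungs were digested with collagenase, red cells were lysed, and the enriched libraries were made by negative selection with antibodies to CD11b, B220, CD3ε and CD146. The deposited matrices hold counts, that is whole numbers of UMIs per gene and cell barcode, with no normalization. Per the file headers they were written by Cell Ranger 3.0.2, and per the submitters' processing notes the reads were aligned to GRCm38. Each matrix held 31053 genes, and no barcode had fewer than 500 UMIs.

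The cell filter, doublet rate, clustering, marker lists, gene lists, comparisons, named-gene rule and the alternatives listed below for deposited barcodes were chosen before the data were examined. Barcodes with at least 200 genes, at least 500 UMIs and at most 15% mitochondrial UMIs were kept. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its own threshold marked 0.139%, 0.0885% and 0.0387% of barcodes in the marrow, enriched lung and total lung libraries, too few to count as a working call. The barcodes with the highest scores were left out at a planned rate of 0.8% per 1000 barcodes, which removed 104, 92 and 53. This left 3506, 3298 and 2531 barcodes. Counts were scaled to 10000 per barcode and log-transformed, and 2000 variable genes were reduced to 30 principal components. A graph of 15 nearest neighbours was clustered with the Leiden method at resolution 1.0, all libraries together.

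A cluster was called "X-like" when at least 3 markers of X reached a 4-fold higher level than in all other barcodes and were seen in at least 10% of its own, provided that a marker was among its 25 leading genes. Clusters with fewer markers, or shallow clusters with no marker among the top 10 genes, stayed unnamed. No authors' cell annotation was deposited, so names may differ from those of the study. Values within a class are given as CPM, a gene's UMIs scaled by the summed UMIs of the class. Shares carry exact (Clopper-Pearson) binomial intervals, UMI sums exact Poisson intervals, and ratios exact conditional intervals, all at 95%. These cover counting error only. With 1 library per group no test of a difference between groups can be made, and cells are not replicates, so no p-value is given. An absence is stated with the limit of 3 counts of the total. For a gene with 0 lung UMIs, "at least N-fold lower" divides the marrow CPM by 3 counts over the lung class; the bound of the ratio interval, which also covers the marrow count, is lower and given beside it.

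For the lung against marrow comparison, the enriched lung library was planned as the lung side, with total lung beside it where it held at least 10 megakaryocyte-like barcodes. The log2 ratios used a pseudocount of 0.5 UMIs. A gene list's median was taken over members with at least 10 summed UMIs, when at least 3 had them. As a description, each median was placed among the medians of 10000 random lists matched on mean CPM in 20 bins. Members of the platelet and proplatelet lists, such as Pf4, Ppbp, Itga2b and Tubb1, were also markers that named the megakaryocyte-like class. The ranks of these lists are therefore not independent of how the barcodes were chosen. Genes were named by a fixed rule. Within the lists, members were counted when their CPM ratio was at least 2 or at most 0.5 with an interval that excluded 1, and 2 to 4 members with the most UMIs or the largest ratio were named. Outside the lists, the 12 genes on each side with the most extreme interval bound nearest 1 were named. They needed at least 20 summed UMIs, a UMI in at least 10% of barcodes of the higher class, and a CPM at least equal to that of the other cells of the same library. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and predicted genes were left out. The function lists covered platelet receptors and granule proteins, megakaryocyte transcription factors, proplatelet and cytoskeleton genes, MHC class II and class I presentation, co-stimulation, pattern recognition, chemokines and cytokines, interferon response, NF-kB response, dissociation stress, cell cycle, hypoxia, haemoglobin and the 4 depletion antibody targets.

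After the data were examined, a further version of every comparison was added, because many cell barcodes occurred in more than 1 library. In it each barcode was kept only in the library where it held the most UMIs (called assigned barcodes below), and filter, doublet removal and clustering were run again. Scrublet's own threshold then marked 0.566%, 0% and 0.379%, and the fixed rate removed 64, 31 and 9 barcodes. The assigned set had 2763, 1928 and 1046 barcodes, with medians of 12745, 4864 and 5934 UMIs. The alternatives were a stricter filter (500 genes, 1000 UMIs, 5% mitochondrial), no mitochondrial limit, no doublet removal, Leiden resolutions of 0.5 and 2.0, and clustering of each library on its own. A marker gate (UMIs of at least 5 of 25 megakaryocyte markers, Pf4 or Ppbp among them) replaced clusters in another. Megakaryocyte-like cells with at least 3 markers of another blood cell class were left out in another. Further alternatives were the mean of per-cell CPM, scaling without abundant gene groups, thinning to 1000 or 500 UMIs, leaving out marrow megakaryocyte-like barcodes over 50000 UMIs (added after the data were examined), pooled lung libraries, centring on the median of genes with at least 20 summed UMIs, a minimum of 30 UMIs per list member, and a pseudocount of 5.

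The ratio intervals were tested on simulated data drawn from the megakaryocyte-like sums of the lung against marrow comparison, with 200 genes changed. The counts were drawn as Poisson counts, which the intervals assume, so differences between barcodes of a class were not simulated. On assigned barcodes 2372 genes were tested, and the interval held the simulated value for 97.8% of 2180 unchanged genes and 98% of 50 genes raised 4-fold. The interval excluded 1 for 80% of the 4-fold higher genes and 31.3% of the 2-fold higher genes, but for only 29.8% of the genes lowered 4-fold and 17.0% of those lowered 2-fold. As deposited these were 46.9%, 20%, 2.08% and 8.16%, so lowered genes were found less often than raised ones. With the pseudocount, unchanged genes had a simulated median log2 ratio of 0.14 on assigned barcodes and 0.66 on barcodes as deposited (8850 unchanged genes of 9046 tested), since the lung sums were small. Among unchanged genes with at least 10 expected lung UMIs it was 0.01 and 0.02. List medians of weakly counted genes therefore carry a bias that the matched random lists share. Coordinates are GRCm38 positions from GENCODE vM21, where 30934 of the 31053 gene identifiers matched. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.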

Results

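Single-cell expression was measured in 3 mouse libraries: bone marrow enriched for megakaryocytes, lung enriched for megakaryocytes, and total lung. Each group had 1 library and no replicate. The marrow library held 61677424 UMIs over 4091 cell barcodes, the enriched lung library 18227795 over 3695, and the total lung library 13362212 over 3352. Median depths were 6713, 1654 and 1429 UMIs per barcode. After filtering, 3506, 3298 and 2531 barcodes remained. All intervals are 95% and cover counting error only.

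The same cell barcodes recurred across libraries. Of 6943 different barcodes, 1846 were present in all 3 libraries and 503 in exactly 2. Nearly every shared barcode had most of its UMIs in 1 library, and in only 3 of 2349 did that library hold under 70% of them. The lesser copy held a nearly fixed fraction of the larger one. Copies of marrow barcodes held a median of 2.65% of the partner's UMIs in enriched lung and 2.53% in total lung. Copies of enriched lung barcodes held 8.83% in marrow and 7.94% in total lung, and copies of total lung barcodes held 8.73% in marrow and 7.47% in enriched lung. Copies made up 24.2%, 41.4% and 49.9% of the barcodes of the marrow, enriched lung and total lung libraries, and 2.45%, 9.97% and 15.2% of their UMIs. Each comparison is therefore given first on the barcodes as deposited and then on assigned barcodes, where each barcode stays only in the library with most of its UMIs. The assigned version was added after the data were examined.

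**Figure D1:**
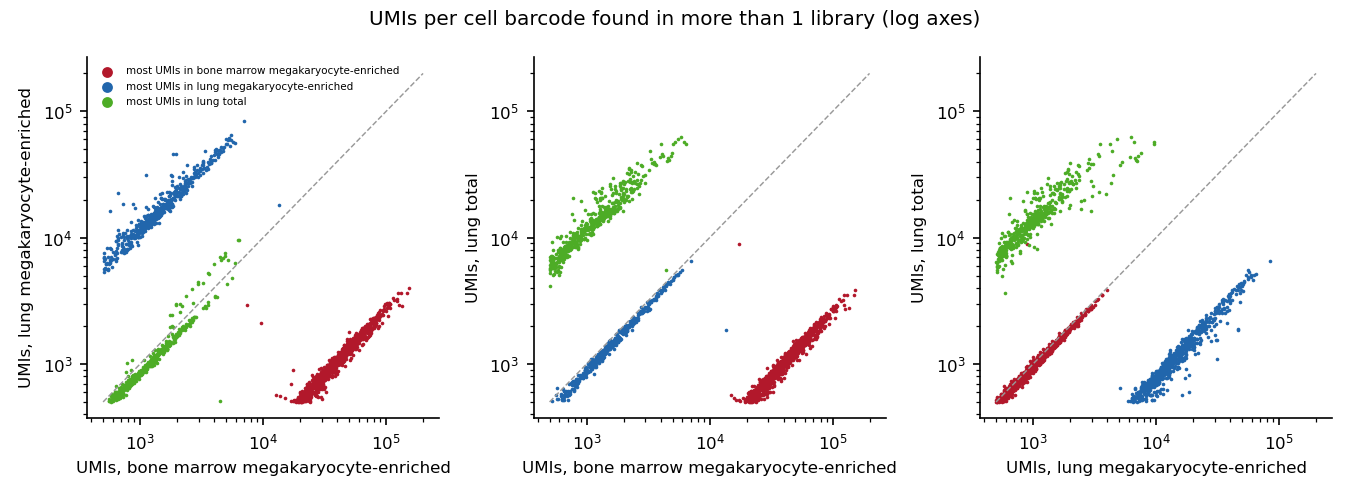
UMIs per cell barcode in each pair of libraries, on log axes, for the 2349 barcodes found in more than 1 library; each point is 1 barcode, coloured by the library with most of its UMIs, and the dashed line marks equal counts. Points lie in narrow bands, at median fractions between 2.53% and 8.83% of the larger count where 1 of the plotted libraries is the dominant one.

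The first comparison asked how many barcodes of a class defined by megakaryocyte and platelet markers each preparation held. The class is called megakaryocyte-like, but its markers do not tell platelets from megakaryocytes. Megakaryocyte-like barcodes, led by the platelet chemokine genes Ppbp and Pf4, the integrin gene Itga2b and the receptor gene Treml1, made up 143 of 3506 marrow barcodes as deposited (4.08%, 3.45 to 4.79). They made up 2 of 3298 in enriched lung (0.0606%, 0.00734 to 0.219) and 22 of 2531 in total lung (0.869%, 0.546 to 1.31). Both enriched lung barcodes were copies of marrow barcodes, and 4 of the 22 in total lung were copies from another library. The marrow cluster was also led by Angpt1 and Sox4, markers of stem and progenitor cells. On assigned barcodes the megakaryocyte-like cluster split from a stem/progenitor-like cluster of 106 marrow barcodes and held 13 of 2763 marrow barcodes (0.471%, 0.251 to 0.803). It held 0 of 1928 enriched lung barcodes, which allows a share of up to 0.156% (the marker gate took in 2, with 5279 and 6763 UMIs), and 17 of 1046 total lung barcodes (1.63%, 0.9495 to 2.59). The 2 gated enriched lung barcodes lay in basophil/mast cell-like and monocyte-like clusters. Over all kept barcodes as deposited, Pf4 stood at 204 CPM in marrow, 25.7 in enriched lung (23.4 to 28.2) and 189 in total lung. Over all kept assigned barcodes, Pf4 stood at 205 CPM in marrow (201 to 209), 1.12 in enriched lung (0.652 to 1.79) and 192 in total lung (184 to 202). The marrow share ranged from 0.114% at resolution 2.0 to 10.7% at resolution 0.5 on deposited barcodes. On assigned barcodes resolution 0.5 named no megakaryocyte-like cluster.

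**Figure D2:**
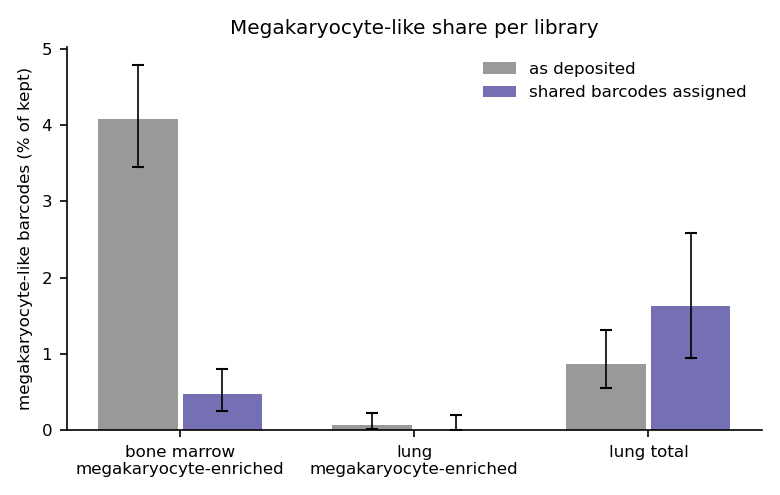
Megakaryocyte-like barcodes as a percentage of kept barcodes in each of the 3 libraries, on barcodes as deposited (grey) and assigned (violet), with exact 95% binomial intervals. The marrow share falls from 4.08% to 0.471% and the total lung share rises from 0.869% to 1.63% in the assigned version, which was also filtered and clustered again; 1 of the 143 marrow barcodes was a copy.

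The megakaryocyte-like barcodes of marrow and lung differed in size and RNA makeup. Of the 13 assigned marrow barcodes, 2 were large, with 153547 and 57841 UMIs, and together held 86.2% of the class's UMIs. The other 11 held 648 to 13962 UMIs, with a median mitochondrial share of 0.0768% and Malat1, a nuclear noncoding RNA, at 474 CPM (271 to 770). The 2 large barcodes had Malat1 at 7392 and 45193 CPM. The 17 total lung barcodes were small, with 584 to 5371 UMIs (median 972), against a median of 6083 in other total lung barcodes. Their median mitochondrial share was 4.39%, and ribosomal protein genes took 2.31% of their UMIs against 15.7% in other total lung barcodes. Malat1 had 4 UMIs among 23913 (167 CPM, 45.6 to 428). Most marrow members also carried at least 3 markers of another blood class: without these, 2 of 13 marrow and 15 of 17 total lung barcodes remained, and 3 of 143 and 18 of 22 as deposited. These markers were counted without thinning, so deeper barcodes reach 3 more readily. Median depths were 1999 UMIs in marrow and 972 in total lung, and 17743 and 989 as deposited.

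The comparison of lung with marrow megakaryocyte-like barcodes addressed how the lung population differs. By clusters the enriched lung library had no megakaryocyte-like barcode of its own. The 2 that passed the marker gate lay in clusters of other blood classes, so the values come from total lung. As deposited, most marrow class barcodes lacked Pf4 and Ppbp: 42 of 143 had a Pf4 UMI and 25 a Ppbp UMI, against 21 and 18 of 22 in lung. Some other members of the platelet list were seen in more of the 143, such as Nrgn in 91 and Tgfb1 in 135. Pf4 was 5.55-fold (5.12 to 6.01) and Ppbp 6.17-fold (5.43 to 6.99) higher in lung. The adaptor gene Nck2 was 59.5-fold higher (29.8 to 115) and Lsm12 27.7-fold (21.5 to 35.3). Malat1 was lower in lung, at a ratio of 0.248 (0.201 to 0.303), and so were Hspa8, a heat-shock chaperone (0.0592, 0.0122 to 0.173), and Npm1, a nucleolar protein (0.106, 0.0388 to 0.230). H2afy and Plac8 had 0 lung UMIs against 5232 and 4574 in marrow. Of platelet receptor and granule genes, 27 of 33 measured members were at least 2-fold higher in lung, 0 lower, and the list median log2 ratio was 2.72, at the 100th percentile of matched random lists. Many of these genes were also markers that named the class, so this rank is not independent of how the barcodes were chosen. Proplatelet and cytoskeleton genes had 17 of 19 members higher and a median of 2.41. MHC class I, dissociation stress and cell cycle genes had 5 of 20, 8 of 18 and 8 of 28 members lower, with medians of -1.44, -2.03 and -1.49. In these lists 8, 7 and 18 measured members had 0 lung UMIs. With those members set to their bound the medians were 0.19, -1.13 and 0.09. The medians of the other lists were -0.39 for transcription factors, 0.27 for MHC class II, 0.83 for co-stimulation, 0.41 for pattern recognition, 1.64 for chemokines and cytokines, 0.71 for interferon response, 0.09 for NF-kB response, 0.34 for hypoxia and 0.47 for haemoglobin. MHC class II members had 6 lung UMIs in all and pattern recognition members 0. The median of all 10390 genes with at least 10 UMIs was 0.26. Pf4, Ppbp and the platelet and proplatelet medians turned to lower in lung at resolution 2.0 (as did the chemokine median), without a mitochondrial limit and with the marker gate, and Malat1 turned to higher in lung with the gate. Without barcodes carrying markers of another blood class, Pf4 turned to a log2 ratio of -0.51 and Malat1 to 3.21. Without the 8 marrow barcodes over 50000 UMIs, the log2 ratios rose to 4.95 for Pf4 and 6.43 for Ppbp, and the platelet and proplatelet medians to 5.87 and 4.01. A pseudocount of 5 turned the transcription factor, MHC class I, dissociation stress and cell cycle medians to above 0, as did resolution 2.0 for MHC class I. The dissociation stress median also did so without a mitochondrial limit and with the marker gate.

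On assigned barcodes, Pf4 (ENSMUSG00000029373, GRCm38 chromosome 5, 90772435 to 90773383) stood at 17522 CPM in lung and 34853 in marrow, a ratio of 0.503 (0.455 to 0.555). Ppbp (ENSMUSG00000029372, chromosome 5, 90768518 to 90770063) had a ratio of 0.480 (0.413 to 0.554). The 2 large marrow barcodes held 3920 of its 4144 marrow UMIs; without them its log2 ratio turned to 0.29 (0.00502 to 0.57), and that of Pf4 was -0.92. With the median of the 1968 genes with at least 20 UMIs (-0.99) set to 0, the 2 log2 ratios were -0.0025 and -0.07. Both lay above the median of all 3378 genes with at least 10 UMIs, which was -1.17. That median equals the value of a gene with 0 lung UMIs, so it depends on the pseudocount. Lying above it does not show that either gene was relatively high in lung. Outside the lists, the highest lung ratio by interval bound was that of Lsm12, an RNA-associated Sm-like protein gene (ENSMUSG00000020922, chromosome 11, 102162497 to 102185296), at 18.7-fold (12.9 to 27.4). It was followed by Lars2, a mitochondrial leucyl-tRNA synthetase (12.8-fold, 10.2 to 16.0), Tsc22d1 (9.20-fold, 7.14 to 11.8) and the histone gene Hist1h2bc (8.28-fold, 6.31 to 10.9). Ptpn18, Ctla2a, AY036118, Nck2, Odc1, Dut, Hist1h4h and S100a10 completed the 12, with ratios from 5.80 (4.10 to 8.13, S100a10) to 11.3 (4.35 to 29.6, Hist1h4h). As deposited Dut had a ratio of 1.17 (0.602 to 2.05), while the other 11 genes were at least 2.92-fold higher (2.07 to 4.01, Ptpn18). The marker gate turned Odc1, Dut and Hist1h4h to lower in lung, at log2 ratios of -0.33, -3.46 and -0.95. Of the 12, 5 were also among the 12 named on deposited barcodes: Lsm12, Tsc22d1, Hist1h2bc, Ctla2a and Nck2. The genes lower in lung were led by Malat1 (ENSMUSG00000092341, chromosome 19, 5795690 to 5802672), at 167 against 15358 CPM, a ratio of 0.0109 (0.00297 to 0.0279). The 2 large marrow barcodes held 3749 of the 3765 marrow Malat1 UMIs and all 227 of Neat1. The other 11 had Malat1 at 474 CPM (271 to 770), an interval that overlaps that of lung, and 0 Neat1 UMIs. Coro1a, an actin-binding protein of leukocytes, had 0 lung UMIs against 283 in marrow, so it was at least 9.20-fold lower (7.43 by its interval). The protease inhibitor genes Slpi (0.0270, 0.000681 to 0.151) and Serpinb1a (at least 6.41-fold lower, 5.16 by its interval), the endoplasmic reticulum chaperones Hspa5 (at least 6.08-fold lower, 4.90 by its interval), Hsp90b1 and Pdia6, and the nuclear RNA Neat1 followed, with Tspan32, Jpt1, Slc14a1 and Tpst2. None of these 12 was among the 12 lower genes named on deposited barcodes. As deposited Slpi was 3.16-fold higher in lung (1.79 to 5.18), Slc14a1 had a ratio of 1.39 (0.508 to 3.05), and only Malat1 and Coro1a (0.221, 0.0603 to 0.568) had an interval below 1. The deposited lung sums include 4 copies from another library. Slpi had 16 lung UMIs as deposited and 1 on assigned barcodes, and Malat1 had 95 and 4. How many of the deposited UMIs the copies held was not counted, so these deposited ratios may not reflect lung barcodes. Scgb1a1, a secreted airway protein picked out after its values were seen, had 205 UMIs in the 17 lung barcodes and a UMI in each of the 1046 assigned total lung barcodes, so a Scgb1a1 UMI does not tell cell types apart in this library.

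**Figure D3:**
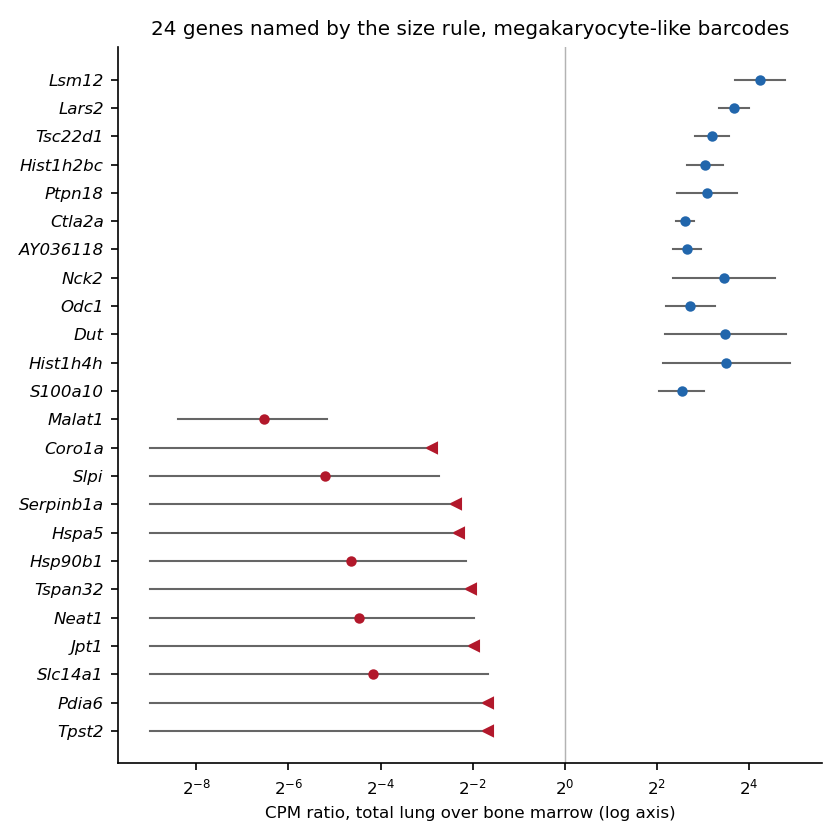
CPM ratio of total lung over bone marrow megakaryocyte-like barcodes (17 and 13, assigned) for the 24 genes of the size rule, on a log axis, with 95% counting intervals. Circles are ratios; left-pointing triangles mark the upper bound of genes with 0 lung UMIs, and intervals that reach beyond the left edge are drawn to it. The 12 upper genes lie at 5.80 or more.

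On assigned barcodes, platelet genes as a group lay near the middle of random lists, and megakaryocyte transcription factors lay low among them. Among platelet receptor and granule genes, 2 of 33 measured members were at least 2-fold higher in lung, 5 were at most 0.5-fold, and 26 were neither. Their median log2 ratio was -0.24 (-0.99 to 0.06), at the 47.0th percentile of random lists. It depended on which barcodes were compared: 5.79 under the stricter filter (169 marrow and 3 lung), 1.80 with each library clustered on its own (110 and 19), 3.60 without barcodes carrying markers of another blood class (2 and 15), 2.08 without the 2 large marrow barcodes (11 and 17) and -1.50 with the marker gate (51 and 66). It was 1.20 with thinning to 1000 UMIs, 0.75 with the mean of per-cell CPM and 0.14 with a pseudocount of 5. Nrgn, a calmodulin-binding protein, was 4.24-fold higher (3.46 to 5.16), and Timp3, a metalloproteinase inhibitor, had 0 lung UMIs against 345 (as deposited 5 against 377, a ratio of 1.28, 0.414 to 3.02). Of megakaryocyte transcription factors, 0 of 15 were higher and 4 lower, with a median of -1.85 (-0.66 with the 7 members at 0 lung UMIs set to their bound) at the 1.56th percentile. This median turned to 0.31 with a pseudocount of 5 and to 0.46 under the stricter filter, and was -0.87 with the mean of per-cell CPM. Mef2c was at least 6.67-fold lower (5.37 by its interval), Zfpm1, the partner of GATA factors, had a ratio of 0.102 (0.00254 to 0.578), and Nfe2 one of 0.781 (0.329 to 1.60), against 3.06 (1.51 to 5.54) as deposited. Proplatelet and cytoskeleton genes had 2 of 19 members higher and 3 lower (median -0.40, 14.4th percentile). In the first 4 of those settings this median was 4.25, 1.57, 0.83 and 1.18, and with thinning 0.46. The platelet tubulin gene Tubb1 was 10.3-fold higher (4.21 to 24.9), Myl6 1.81-fold (1.58 to 2.07), while Tuba4a (0.394, 0.274 to 0.549) and Actn1 (0.236, 0.0857 to 0.520) were lower. As deposited these 2 were 4.10-fold (3.13 to 5.27) and 2.27-fold (0.905 to 4.74) higher. MHC class I genes had 1 of 12 members higher and 2 lower (median -0.23, 75.4th percentile; 0.92 with a pseudocount of 5). H2-T23 was 3.11-fold higher (1.37 to 6.45), B2m had a ratio of 1.45 (0.983 to 2.09) and H2-D1 one of 1.55 (0.954 to 2.42), and the chaperone gene Calr was at least 10.7-fold lower (8.68 by its interval).

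Smaller groups had few measured members. Interferon response genes had 0 of 4 higher and 2 lower, Ifitm2 (0.196, 0.0400 to 0.583) and Ifitm3 (0.435, 0.196 to 0.842), with a median of -1.21 (0.71 as deposited). The interferon median turned to above 0 under the stricter filter and with the marker gate. Chemokine and cytokine genes had 0 of 3 past either limit (median -1.60), with Tgfb1 at 0.630 (0.417 to 0.917) and Cxcl5 at 0.214 (0.00530 to 1.25), against 3.24 (2.32 to 4.40) and 2.01 (0.0500 to 11.8) as deposited. Dissociation stress genes had 1 of 5 lower, Jund, whose interval reached 0.990. None of the 5 had a lung UMI (median -2.71, or -0.10 with the 5 set to their bound), while Jun had 33 UMIs in marrow. Cell cycle genes had 1 of 3 lower, H2afz (0.313, 0.0840 to 0.821), with Tubb5 at 0.285 (0.0338 to 1.07) and a median of -1.50. Hypoxia genes had 1 of 3 lower, the lactate dehydrogenase gene Ldha (0.128, 0.0347 to 0.331; 0.993, 0.566 to 1.62, as deposited), with Pgk1 at 0.427 (0.0503 to 1.63) and a median of -0.92. Haemoglobin genes had 1 of 3 higher, Hba-a1 at 19.0-fold (9.58 to 39.4), with Hbb-bs at 2.24 (0.835 to 5.17) and a median of 1.24 that the mean of per-cell CPM turned to -1.08. Fcer1g, the only measured co-stimulation gene, had a ratio of 0.559 (0.309 to 0.939), against 2.34 (1.49 to 3.51) as deposited, and the NF-kB list had 1 measured member, at a log2 ratio of -1.40. MHC class II genes had 3 lung UMIs and 8 in marrow, pattern recognition genes 0 and 19, and the depletion antibody targets 1 and 3. With the median of genes with at least 20 UMIs set to 0, Tgfb1, Fcer1g and the platelet, proplatelet, MHC class I and hypoxia medians turned to above 0. The chemokine, dissociation stress and hypoxia medians did so with each library clustered on its own, with the marker gate and with a pseudocount of 5. Pf4, Ppbp, Tuba4a, Actn1, Ifitm3, Tgfb1 and Fcer1g turned to higher in lung under the stricter filter and under clustering of each library on its own. Ppbp also turned to a log2 ratio of 1.12, and Tgfb1 to 1.15, without barcodes carrying markers of another blood class. Without the 2 large marrow barcodes Actn1 turned to 1.03 and Tgfb1 to 0.55. Malat1, Neat1, Coro1a, Slpi, Ifitm2, Ifitm3, Fcer1g and Jund turned to higher in lung with the marker gate, and so did Neat1, Coro1a and Slpi with each library clustered on its own. Timp3 and Slc14a1 did so under the stricter filter.

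Enriched and total lung were compared for what the negative selection left. Whether the enriched lung files hold the preparation that their label names was not settled, since on assigned barcodes they held no megakaryocyte-like barcode by clusters and 17 Pf4 UMIs. The 2 barcodes that passed the marker gate there lay in clusters of other blood classes. Epithelial-like barcodes, most of them in clusters led by club cell genes such as Scgb1a1, were the largest named class of the enriched library. They made up 1228 of 3298 barcodes as deposited (37.2%, 35.6 to 38.9) and 688 of 2531 in total lung (27.2%, 25.5 to 29.0). On assigned barcodes they were 1492 of 1928 in enriched lung (77.4%, 75.5 to 79.2) and 364 of 1046 in total lung (34.8%, 31.9 to 37.8). Cluster 23 held 817 of the first and cluster 24 held 153 of the second. Named blood cell classes other than megakaryocytes were 973 of 3298 barcodes in enriched lung as deposited (29.5%, 27.9 to 31.1) and 1176 of 2531 in total lung (46.5%, 44.5 to 48.4). On assigned barcodes they were 3.53% of enriched lung (68 barcodes, 2.75 to 4.45) and 39.7% of total lung (415 barcodes, 36.7 to 42.7). In total lung these were mainly macrophage-like (165), monocyte-like (105) and neutrophil-like (70) barcodes. Transcripts of 3 of the 4 antibody targets were lower in enriched lung, and for Cd3e the interval of the ratio included 1. The total over enriched CPM ratio was 26.6 for Itgam, which encodes CD11b (20.7 to 34.7), 19.4 for Ptprc, which encodes the protein bearing B220 (17.5 to 21.5), 10.4 for Mcam, which encodes CD146 (5.11 to 23.9), and 4.93 for Cd3e (0.881 to 49.9). As deposited the ratios were 11.5, 10.5, 6.55 and 3.14. Megakaryocyte genes that the antibodies do not target were lower in enriched lung as well. On assigned barcodes Pf4 stood at 192 CPM in total lung and 1.12 in enriched lung, Ppbp at 33.0 and 0.461, and Itga2b at 21.2 and 1.05. The epithelial gene Epcam stood at 33.0 and 32.1. The target ratios therefore do not set the antibodies' effect apart from a wider loss of blood cell transcripts. Scgb1a1 alone took 41.7% of the kept UMIs of enriched lung and 10.1% of those of total lung. Of the enriched lung epithelial-like barcodes, 85.4% (83.5 to 87.1) had under 0.5% mitochondrial UMIs, and these had Malat1 at 46.5 CPM; in total lung 23.4% (19.1 to 28.0) did. The enriched lung epithelial-like share was 5.29% when each library was clustered on its own, below the 28.2% then found in total lung. In that setting, cluster markers had to stand 4-fold above the other barcodes of the same library. In enriched lung Scgb1a1 had a UMI in each of the 1928 barcodes, so the low share does not show fewer epithelial cells.

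MHC class II transcripts were compared because the study's title concerns immune functions of lung megakaryocytes. The sum of H2-Aa, H2-Ab1, H2-Eb1 and Cd74, the class II chains and their chaperone, was 126 CPM (34.4 to 323) in the 22 megakaryocyte-like barcodes of total lung as deposited, and 38381 (37781 to 38989) in dendritic cell-like ones. As deposited it was also 14745 in B cell-like, 1186 in macrophage-like and 4072 in monocyte-like barcodes of total lung. On assigned barcodes it was 125 CPM (25.9 to 367; 3 UMIs, at the limit of 3 counts) in the 17 megakaryocyte-like barcodes. It was 14599 (14204 to 15003) in B cell-like, 1679 (1621 to 1738) in macrophage-like and 1457 (1377 to 1540) in monocyte-like barcodes. It was 169 (143 to 197) in fibroblast-like barcodes, within the megakaryocyte-like interval, and 21.1 (4.36 to 61.8; 3 UMIs) in erythroid-like ones; which of these is background was not settled. Epithelial-like barcodes had 234 (214 to 255), with 2717 in the cluster led by the alveolar type II gene Sftpc and 35.8 in the largest club gene cluster of total lung. Marrow megakaryocyte-like barcodes had 87.5 CPM (77.3 to 98.6, from 268 UMIs) as deposited, within the interval of lung as deposited. On assigned barcodes they had 8.16 CPM (0.988 to 29.5, from 2 UMIs). After thinning to 1000 UMIs, 0 of 8 lung megakaryocyte-like barcodes had a class II UMI, which allows a share of up to 37.5%, with 9 shallower ones left out; before thinning 17.6% did. The thinned share was 11.7% (4.82 to 22.6) in fibroblast-like barcodes, with 11 left out (46.5% before thinning), and 100% (87.2 to 100) in B cell-like ones, with 0 left out. Median depths were 972, 12586 and 12826 UMIs. Without a mitochondrial limit the deposited megakaryocyte-like level was 1587 CPM (1413 to 1776), over 77 barcodes. With the marker gate in place of clusters the assigned level was 4630 CPM, since the gate took in 49 barcodes outside the megakaryocyte-like class.

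**Figure D4:**
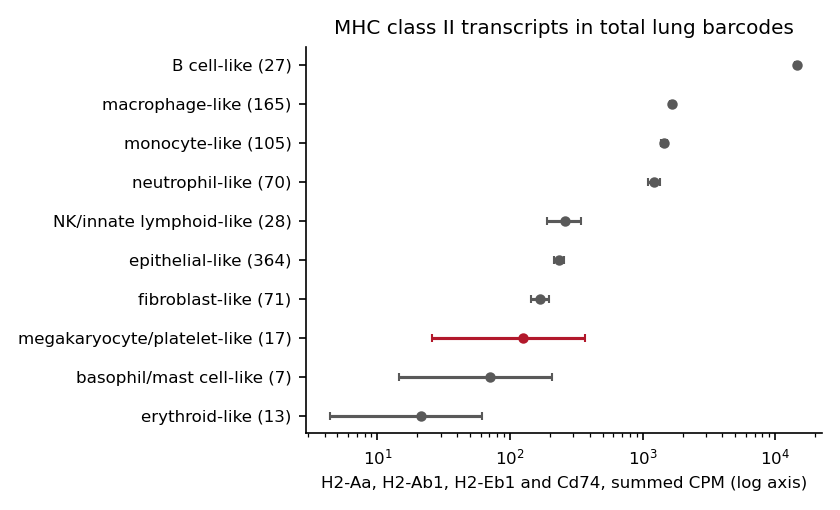
Summed CPM of H2-Aa, H2-Ab1, H2-Eb1 and Cd74 on a log axis for each named class of assigned total lung barcodes (barcode numbers in brackets), with exact 95% Poisson intervals. The megakaryocyte-like class, in red, stands at 125 CPM, below B cell-like (14599), macrophage-like (1679) and monocyte-like (1457) barcodes.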

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

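All tests in this part were chosen after the result they address had been seen. The cell barcodes themselves are data that no comparison used, and 1846 of them occurred in all 3 libraries, where a count of 0 would allow 3. Chance use of the same barcode by unrelated droplets is argued against by the UMI counts: 97.9% of 4195 copies (97.5 to 98.4) lay within 1.5 times the median UMI ratio of their pair of libraries, against 45.1% with shuffled partners. Molecules of 1 library counted in another are consistent with the profiles: among 100 barcodes of the dominant library, 99.8% of 1800 copies (99.4 to 99.9) correlated best with the one of the same sequence, where chance gives 1%. A copy was present for 3171 of 3576 barcodes whose expected copy had at least 750 UMIs, from 66.8% of enriched lung barcodes in marrow to 99.9% of marrow barcodes in enriched lung, and for 1 of 6056 whose expected copy had fewer than 250. No deposited barcode held fewer than 500 UMIs, so the last count follows from that limit and bears on no explanation. The step at which the sharing of barcodes arose stays open, and no biological explanation was tested.

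The lung megakaryocyte-like barcodes held little Malat1 (167 CPM, 45.6 to 428). Megakaryocytes poor in Malat1 in any tissue stay open: the lower of the 2 large marrow barcodes had 7392 CPM (6968 to 7835), but the other 11 marrow barcodes together had 474 (271 to 770), an interval that overlaps that of lung. A lack of nuclear RNA in shallow barcodes of this library, whatever their class, stays open as well: 84.0% of 244 other total lung barcodes of up to 1500 UMIs had no Malat1 UMI (78.8 to 88.4), against 73.3% of the 15 megakaryocyte-like ones (44.9 to 92.2), yet summed Malat1 was 1106 CPM in the former (968 to 1258) and 275 in the latter (75.0 to 704). The share without Malat1 was 98.7% in macrophage-like, 76.5% in epithelial-like and 73.3% in fibroblast-like barcodes of that depth. The 2 megakaryocyte-like barcodes over 1500 UMIs had 0 Malat1 UMIs in 9373 (a count of 0 allows 320 CPM), against 17055 CPM in 266 others of 1500 to 6000 UMIs, of which 44.4% had none. Platelets or other anucleate fragments may also be present, but at 500 UMIs per barcode Malat1 was seen in 0 of 17 megakaryocyte-like barcodes, which allows 17.6%, and in 13.1% of the other shallow barcodes (9.15 to 18.0), so this detection of Malat1 cannot tell fragments from shallow barcodes. The 2 groups of up to 1500 UMIs did differ in ribosomal protein genes, which took 3.09% of UMIs in megakaryocyte-like and 18.7% in other barcodes. Whether that marks fragments was not tested. A biological difference between lung and marrow megakaryocytes stays open as well.

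Outside the megakaryocyte-like class, 49 of 1029 total lung barcodes (4.76%, 3.54 to 6.25) passed the gate of at least 5 megakaryocyte markers, a signal that the class-based comparisons leave out. They included 9 neutrophil-like, 7 monocyte-like and 5 macrophage-like barcodes and 24 of unnamed clusters, and their class II level was 4815 CPM (4638 to 4996). Free RNA spread evenly is argued against as the only source: at 1000 UMIs per barcode, 6.30% of 349 named blood cell barcodes (3.99 to 9.39) and 1.79% of 335 epithelial-like and fibroblast-like ones (0.660 to 3.86) had a UMI of 11 specific genes such as Ppbp, Itga2b and Gp9 (unthinned 24.4% and 11.6%, median depths 7267 and 5023). At 1000 UMIs such a UMI was seen in 7 of 65 neutrophil-like, 6 of 105 monocyte-like and 7 of 104 macrophage-like barcodes. It was seen in 0 of 27 B cell-like barcodes, which allows 11.1%, and in 0 of 28 NK/innate lymphoid-like ones, which allows 10.7%. Before thinning 0 of the 27 and 5 of the 28 had one, so a lower share in these classes is not shown. Doublets with a called megakaryocyte-like barcode were expected to number 0.285, far below 49. Platelet or megakaryocyte material caught in the same droplets is consistent with co-occurrence, since 10 other specific genes had an 8.47-fold higher CPM (5.74 to 12.3) in the 19 blood cell barcodes with a Ppbp UMI than in those without, while attachment before capture and the leukocytes' own expression stay open.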

How the results depend on the processing

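In each setting the values of deposited barcodes come first, log2 ratios and list medians are of total lung over marrow, and the cause was not tested unless stated. All alternatives on assigned barcodes were, like the assignment itself and the limit of 50000 UMIs, chosen after the data had been examined. With 1 library per group no library could be left out, and depth limits the gene values: the lung class held 23913 UMIs on assigned barcodes. A value is called reversed when its interval excluded 0 and its sign changed; other changes beyond the interval, with or without a change of sign, are called moved. Over all alternatives, gene values stayed in 79 cases on deposited and 421 on assigned barcodes, moved in 83 and 155 and reversed in 14 and 37. List medians stayed in 145 and 76 cases, moved in 52 and 34 and reversed in 14 and 15. All but the moved genes are listed below, with the numbers of megakaryocyte-like barcodes in brackets where these were chosen anew (143 marrow and 22 total lung as deposited, 13 and 17 assigned). No value could be had for the MHC class II list median on assigned barcodes, nor for any gene or list there at resolution 0.5, which named no megakaryocyte-like cluster. Pooling the lung libraries changed nothing on assigned barcodes, since enriched lung added none, and on deposited barcodes moved Pf4 to 2.70, Malat1 to -1.52 and Ctla2a to 4.22. Genes named only on assigned barcodes were not run on deposited ones; the report gives the deposited ratios that lie on the other side of 1.

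Under the stricter filter (211 marrow and 4 total lung), the megakaryocyte-like share was 9.60% in marrow and 0.472% in total lung, and the epithelial-like share was 51.6% in enriched lung and 21.0% in total lung. Other blood classes made up 70.7% in total lung, and the class II level was 0 CPM (a count of 0 allows 248). List medians moved to platelet 5.65, proplatelet 4.11, MHC class II 2.42, co-stimulation 3.48, pattern recognition 2.53, chemokine 2.75, interferon 2.21 and hypoxia 1.42. Under the stricter filter on assigned barcodes (169 marrow and 3 total lung), the megakaryocyte-like share was 8.57% in marrow and 0.477% in total lung, and the epithelial-like share was 41.5% in enriched lung and 20.2% in total lung. The share of other blood classes was 54.5% in total lung, and the class II level was 0 CPM (a count of 0 allows 276). List medians moved to platelet 5.79, proplatelet 4.25, interferon 2.42, dissociation stress -0.85 and cell cycle -1.85, and list medians reversed to transcription factor 0.46, chemokine 3.27 and hypoxia 1.66. Genes reversed to Pf4 5.57, Ppbp 6.29, Timp3 2.89, Tuba4a 2.09, Actn1 4.07, Ifitm3 1.54, Fcer1g 1.91, Tgfb1 3.02 and Slc14a1 1.94.

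Without a mitochondrial limit (14 marrow and 77 total lung), the megakaryocyte-like share was 0.390% in marrow, 0.272% in enriched lung and 2.94% in total lung, and the epithelial-like share was 56.5% in enriched lung and 24.1% in total lung. Other blood classes made up 24.8% in enriched lung and 39.3% in total lung, and the class II level was 1587 CPM. List medians moved to transcription factor -2.86, MHC class II 6.22, interferon -0.82, NF-kB 4.09, cell cycle -2.29 and hypoxia -1.86, and list medians reversed to platelet -2.51, proplatelet -2.69 and dissociation stress 1.94. Genes reversed to Pf4 -3.28, Ppbp -3.48, Ctla2a -0.0126 and Plac8 1.45. Without a mitochondrial limit on assigned barcodes (13 marrow and 21 total lung), the epithelial-like share was 62.6% in enriched lung, and the share of other blood classes was 50.4% in total lung. List medians moved to chemokine -1.97 and cell cycle -1.87.

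Without doublet removal (121 marrow and 24 total lung), the megakaryocyte-like share was 3.35% in marrow, and the epithelial-like share was 43.0% in enriched lung and 29.4% in total lung. The share of other blood classes was 27.0% in enriched lung and 43.4% in total lung. Without doublet removal on assigned barcodes (13 marrow and 17 total lung), the epithelial-like share was 58.1% in enriched lung.

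At resolution 0.5 (375 marrow and 27 total lung), the megakaryocyte-like share was 10.7% in marrow, and the epithelial-like share was 57.7% in enriched lung and 35.1% in total lung. Other blood classes made up 25.1% in enriched lung and 40.5% in total lung, and list medians moved to platelet 4.74, proplatelet 3.42, MHC class II 1.54, chemokine 2.70 and interferon 1.52. At resolution 0.5 on assigned barcodes (0 marrow and 0 total lung), the megakaryocyte-like share was 0% in marrow and 0% in total lung, and the epithelial-like share was 93.6% in enriched lung. The share of other blood classes was 45.1% in total lung.

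At resolution 2.0 (4 marrow and 19 total lung), the megakaryocyte-like share was 0.114% in marrow, and the epithelial-like share was 22.98% in enriched lung and 25.2% in total lung. Other blood classes made up 42.8% in total lung, and list medians moved to MHC class I 0.36 and hypoxia -1.14. List medians reversed to platelet -0.38, proplatelet -0.59 and chemokine -2.05, and genes reversed to Pf4 -0.67 and Ppbp -1.01. At resolution 2.0 on assigned barcodes (13 marrow and 17 total lung), the epithelial-like share was 58.0% in enriched lung.

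With each library clustered on its own (106 marrow and 19 total lung), the megakaryocyte-like share was 3.02% in marrow and 0% in enriched lung, and the epithelial-like share was 4.37% in enriched lung and 17.2% in total lung. The share of other blood classes was 40.9% in enriched lung and 49.5% in total lung, and list medians moved to dissociation stress -3.11. Markers here had to stand 4-fold above the other barcodes of the same library, so a class that fills most of a library can go unnamed. With each library clustered on its own on assigned barcodes (110 marrow and 19 total lung), the megakaryocyte-like share was 3.98% in marrow, and the epithelial-like share was 5.29% in enriched lung and 28.2% in total lung. Other blood classes made up 1.04% in enriched lung and 47.1% in total lung, and list medians moved to platelet 1.80, proplatelet 1.57 and cell cycle -1.84. List medians reversed to chemokine 1.23, dissociation stress 0.15 and hypoxia 0.15, and genes reversed to Pf4 1.25, Ppbp 1.64, Tuba4a 0.75, Actn1 0.27, Ifitm3 1.41, Fcer1g 2.52, Tgfb1 0.88, Coro1a 0.47, Slpi 0.65 and Neat1 0.69.

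With the marker gate (54 marrow and 70 total lung), the megakaryocyte-like share was 1.54% in marrow, 0.243% in enriched lung and 2.77% in total lung, and the class II level was 4750 CPM. List medians moved to transcription factor -1.71, MHC class II 5.80, co-stimulation 4.36, pattern recognition 3.25, chemokine 2.31, interferon 2.42, NF-kB 3.22 and cell cycle -4.84, and list medians reversed to platelet -1.32, proplatelet -0.23 and dissociation stress 1.996. Genes reversed to Pf4 -2.02, Ppbp -2.10, Malat1 0.41 and Plac8 2.09. With the marker gate on assigned barcodes (51 marrow and 66 total lung), the megakaryocyte-like share was 1.85% in marrow and 6.31% in total lung, and the class II level was 4630 CPM. List medians moved to platelet -1.50, interferon 2.46 and cell cycle -4.82, and list medians reversed to chemokine 2.23, dissociation stress 2.09 and hypoxia 0.22. Genes reversed to Ifitm2 0.87, Ifitm3 2.46, Fcer1g 2.64, Jund 0.94, Odc1 -0.33, Dut -3.46, Hist1h4h -0.95, Malat1 0.41, Coro1a 1.52, Slpi 1.43 and Neat1 1.38.

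Without cells with markers of another blood class (3 marrow and 18 total lung), list medians moved to platelet 1.63 and proplatelet 0.62, and genes reversed to Pf4 -0.51 and Malat1 3.21. Without cells with markers of another blood class on assigned barcodes (2 marrow and 15 total lung), list medians moved to platelet 3.60 and proplatelet 0.83, and genes reversed to Ppbp 1.12 and Tgfb1 1.15.

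With the mean of per-cell CPM, list medians moved to platelet 3.37. With the mean of per-cell CPM on assigned barcodes, list medians moved to platelet 0.75, transcription factor -0.87, chemokine -0.27 and cell cycle -2.74, and list medians reversed to haemoglobin -1.08.

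With scaling without the abundant gene groups, list medians moved to MHC class I -1.80. With scaling without the abundant gene groups on assigned barcodes, list medians moved to chemokine -1.71 and cell cycle -1.62.

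With thinning to 1000 UMIs, list medians moved to platelet 4.23 and interferon -1.17. With thinning to 1000 UMIs on assigned barcodes, list medians moved to platelet 1.20 and proplatelet 0.46.

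With members of at least 30 UMIs, list medians moved to chemokine 0.43.

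With a pseudocount of 5, list medians moved to transcription factor 1.17, MHC class II 2.47, MHC class I 0.56, co-stimulation 3.39, pattern recognition 3.56, chemokine 3.96, interferon 3.66, NF-kB 2.95 and hypoxia 3.302, and list medians reversed to dissociation stress 0.15 and cell cycle 1.11. With a pseudocount of 5 on assigned barcodes, list medians moved to platelet 0.14, MHC class I 0.92 and cell cycle -0.10, and list medians reversed to transcription factor 0.31, chemokine 0.21, dissociation stress 0.43 and hypoxia 0.44.

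Without marrow barcodes over 50000 UMIs (135 marrow and 22 total lung), list medians moved to platelet 5.87 and proplatelet 4.01. Without marrow barcodes over 50000 UMIs on assigned barcodes (11 marrow and 17 total lung), list medians moved to platelet 2.08 and proplatelet 1.18, and genes reversed to Ppbp 0.29, Actn1 1.03 and Tgfb1 0.55.

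With shared barcodes assigned and clustering run again, the megakaryocyte-like share was 0.471% in marrow, 0% in enriched lung and 1.63% in total lung, and the epithelial-like share was 77.4% in enriched lung and 34.8% in total lung. The share of other blood classes was 3.53% in enriched lung and 39.7% in total lung, and list medians moved to transcription factor -1.85, interferon -1.21, dissociation stress -2.71 and hypoxia -0.92. List medians reversed to platelet -0.24, proplatelet -0.40 and chemokine -1.60, and genes reversed to Pf4 -0.99 and Ppbp -1.06.

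With the median of genes with at least 20 UMIs set to 0 on assigned barcodes, list medians moved to platelet 0.75, transcription factor -0.86, proplatelet 0.58, MHC class I 0.76, chemokine -0.61 and cell cycle -0.51, and list medians reversed to hypoxia 0.0678. Genes reversed to Fcer1g 0.19 and Tgfb1 0.34.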

Other observations

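The values in this part were chosen after the data had been examined, and no explanation of them was tested. The marrow library held a graded set of blood cell classes that the comparisons above did not describe. On assigned barcodes, 1071 of 2763 were erythroid-like (38.8%, 36.9 to 40.6), led by haemoglobin genes, Alas2 and Car1. Monocyte-like (482), neutrophil precursor-like (380), neutrophil-like (325) and basophil/mast cell-like (123) barcodes followed. A stem/progenitor-like cluster of 106 barcodes, led by Ctla2a, Angpt1, Sox4 and Meis1, also carried megakaryocyte transcripts, and 24 of the 106 (22.6%, 15.1 to 31.8) passed the marker gate. In it Itga2b stood at 160 CPM (144 to 177) against 11.2 in the other marrow barcodes outside the megakaryocyte-like class, and Pf4 at 1193 (1149 to 1238) against 5.45, with a Pf4 UMI in 28 of 106 barcodes. The late granule gene Ppbp was at 7.27 CPM (4.24 to 11.6) against 16904 in the megakaryocyte-like barcodes, and Mki67, a proliferation marker, at 86.9 CPM (75.3 to 99.7) against 563 in the other marrow barcodes.

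Lung epithelial-like barcodes fell into clusters led by club cell genes (Scgb1a1, Cyp2f2), by secretory genes such as Bpifa1, Scgb3a1 and Muc5b, by alveolar type II genes (Sftpc, Lamp3) and by alveolar type I genes (Ager). The last cluster held 64 total lung barcodes and 1 of enriched lung. Of all 1928 assigned enriched lung barcodes, 85.2% (83.6 to 86.8) had under 0.5% mitochondrial UMIs, against 10.4% in total lung (8.63 to 12.4) and 13.7% in marrow (12.5 to 15.1). Of these 1643 enriched lung barcodes, 1274 were epithelial-like, 348 were in unnamed clusters and 14 were erythroid-like. The largest unnamed cluster of that library, with 313 barcodes, was led by B430010I23Rik, Nupr1 and Dcxr. In the enriched lung barcodes below that limit Malat1 stood at 42.4 CPM, and in the others at 4740. In total lung, 357 of 1679 assigned barcodes (21.3%) exceeded the limit of 15% mitochondrial UMIs, against 36 of 2164 in enriched lung. An unnamed total lung cluster of 126 barcodes, led by Ifi27l2a, Nr4a1 and Atf3 with Cd74 and H2-Aa, had a class II level of 4861 CPM, and 23 of its barcodes (18.3%, 11.9 to 26.1) passed the megakaryocyte marker gate. Another unnamed cluster, led by H2-Ab1, H2-Aa and Cd74, had 171 marrow and 32 total lung barcodes, with class II levels of 1056 and 35450 CPM.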
